A study of Mus musculus with 9 samples.

How the data were processed

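Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the nuclear protein DPPA4 was measured in 3 mouse cell lines, with 2 immunoprecipitated libraries and 1 input library per line. The 6 immunoprecipitated libraries each have a deposited peak list. The 3 input libraries entered no comparison here. Libraries were made from sonicated nuclei with a Nextera kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, bcl2fastq 1.8, BWA 0.7.13-r1126, SAMtools 1.3 and the genome build mm9. The peak names in the deposited lists begin with MACS, the name of a peak caller. Its version, its threshold and whether the input served as its control are not given in the sources used here. The authors called peaks in each library separately, so each list is 1 replicate.

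Each deposited list holds 5 columns, namely the chromosome, start, end and name of a peak and the score given by the authors' peak caller. The scale of the deposited score is not named in the files. It ran from 50 upwards in every list, and many peaks of the E14 and P19 lists were tied at 3100. Peaks at 3100 or above numbered 198 and 140 in the E14 libraries, 1399 and 2108 in the P19 libraries, and 1 and 16 in the 3T3 libraries. Scores were therefore turned into percentile ranks within a list (100 for the strongest peak), and no score was compared between lists as a measure of amount. Read depth is unknown, since the lists hold no read counts. Intervals on shares are Wilson 95% intervals, which cover counting error only and treat peaks as independent. Coordinates are printed 1-based in mm9.

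Samples were grouped by the cell line and the replicate number in their titles. Nothing in the labels says whether the 2 libraries of a line came from separate cultures, so the spread between them may be technical. Peaks were taken to overlap when they shared at least 1 bp. A reproducible region of a line was the union of overlapping peaks of its 2 libraries. Regions of the lines were merged where they overlapped and sorted into the 7 combinations of lines. For a pair of lines, the share was that of the smaller set of regions that overlapped the other set. Chance overlap came from 100 circular shifts of a list along each chromosome, within the span of the observed peaks. The smallest one-sided p that 100 shifts can give is 0.0099. The shifts take no account of assembly gaps, mappability or open chromatin. Agreement of libraries was measured by the base-pair Jaccard index, the length shared by 2 lists over the length covered by either. Same-line agreement was tested by an exact permutation test over the 15 ways to pair 6 libraries, whose smallest p is 0.067. A comparison of 2 libraries with 2 others cannot give an exact two-sided p under 0.333. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The overlap code was tested on 29151 simulated sites, and it returned between 99.2% and 100.3% of the regions placed in each combination of lines.

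Regions to be named were chosen by a rule fixed before the data were examined, namely the 3 regions of each combination with the highest mean percentile over the libraries of its lines. The tests, the alternatives and the 14 gene lists were fixed then too. The shares by score decile, the shares with a peak in any library and the rank correlations between libraries were not among them. The gene table at hand belongs to another assembly than mm9 (GRCm38), so no peak was assigned to a gene. The planned promoter shares, counts of genes with a promoter peak, tests of the 14 gene lists and naming of genes were therefore not run. Alternatives were an overlap of 50% of the shorter peak, the best-scoring 50% of each list, lists limited to the 15462 best peaks (the length of the shortest), autosomes alone, peaks of either library, a replicate block and leaving out each library. Setting each peak to 500 bp around its midpoint was added after the data were seen.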

Results

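Dppa4 binding was mapped by ChIP-seq in 3 mouse cell lines. E14 is an embryonic stem cell line, grown here without feeder cells in 2i medium. P19 is an embryonal carcinoma line, derived from a teratocarcinoma and able to differentiate. 3T3 is a fibroblast line, and the cells used here carried Dppa4 ectopically. Each line gave 2 immunoprecipitated libraries. The comparisons ask where DPPA4 lies in each line, how far the sites of the 2 pluripotent lines coincide, and how far DPPA4 placed in fibroblasts is found at the same sites.

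E14 and P19 cells gave about 3 times as many Dppa4 peaks as 3T3 cells. The E14 libraries held 61693 and 43443 peaks, a mean of 52568 ± 12905 (SD, n = 2). The P19 libraries held 40011 and 51196 peaks, a mean of 45604 ± 7909 (SD, n = 2). The 3T3 libraries held 15462 and 17540 peaks, a mean of 16501 ± 1469 (SD, n = 2). The E14 mean was 3.19-fold and the P19 mean 2.76-fold the 3T3 mean. The lowest E14 or P19 library held more peaks than the highest 3T3 library, but 2 libraries against 2 cannot give an exact two-sided p under 0.333. Peaks were wider in replicate 2 of each line, with medians of 411 and 772 bp in E14, 453 and 540 bp in P19, and 400 and 872 bp in 3T3. The covered length was 34.5 ± 4.64 Mb in E14, 27.5 ± 7.83 Mb in P19 and 12.4 ± 6.70 Mb in 3T3 (SD, n = 2). The number of reads behind each list is unknown, so the lists do not show whether a missing peak is an unbound site or a site below detection.

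Replicate lists of a line shared most of their peaks. In E14, 66.7% of the peaks of replicate 1 and 86.5% of those of replicate 2 overlapped a peak of the other library. The shares were 87.7% and 65.2% in P19, and 86.8% and 63.9% in 3T3. In each line the shorter list was the one contained to the larger share. Circular shifts of the lists gave between 0.868% and 3.17% on average, and no shift reached an observed share (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). The base-pair Jaccard index was 0.53 between the E14 libraries, 0.55 between the P19 libraries and 0.39 between the 3T3 libraries. Between E14 and P19 libraries it ranged from 0.43 to 0.51. It ranged from 0.16 to 0.27 between E14 and 3T3 libraries and from 0.16 to 0.25 between P19 and 3T3 libraries. Of the 15 ways to pair the 6 libraries, pairing by cell line gave the highest mean index, 0.491 against 0.456 for the next (exact permutation p = 0.067, the smallest possible with 15 pairings). The index cannot exceed the shorter covered length over the longer one. The 3T3 libraries covered 7.62 and 17.1 Mb, the E14 libraries 31.2 and 37.8 Mb and the P19 libraries 22.0 and 33.1 Mb. Covered length thus limits the values with 3T3 and enters the pairing result. The low values do not by themselves show different sites.

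**Figure D1:**
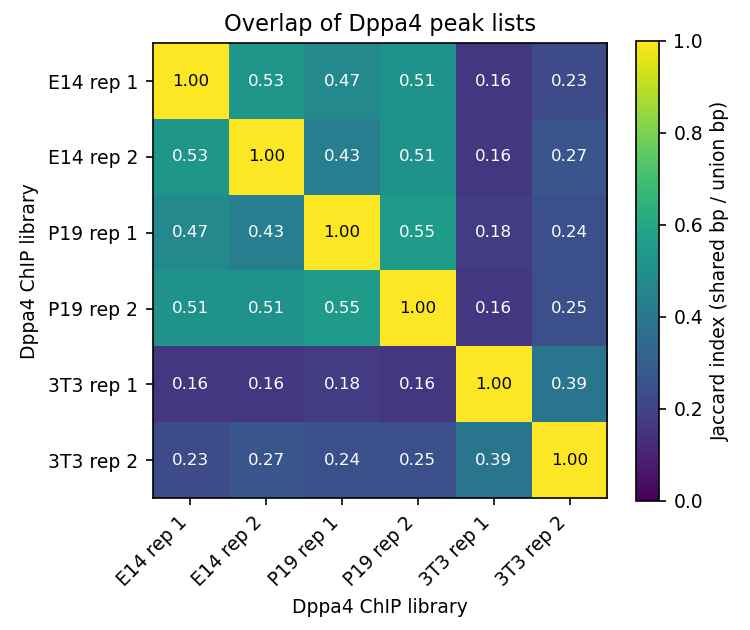
Base-pair Jaccard index (shared bp over bp covered by either list, no unit) between the peak lists of the 6 Dppa4 ChIP libraries, with libraries on both axes. E14 and P19 libraries lie between 0.43 and 0.51, close to the same-line values of 0.53 and 0.55 and above the 0.39 of the 3T3 libraries. Pairs of a 3T3 library with an E14 or P19 library lie at 0.27 or below, where the shorter length covered by 3T3 limits the index. The unequal lengths covered by the 3T3 libraries (7.62 and 17.1 Mb) also limit the index between them.

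Regions found in both libraries numbered 37337 in E14, 32963 in P19 and 11178 in 3T3. Merged over the lines they made 45616 regions. Regions held by E14 and P19 but not 3T3 were the most frequent kind, with 18315 regions or 40.2% of the total. Another 7042 regions (15.4%) were held by all 3 lines. E14 alone held 10040 regions, P19 alone 6234 and 3T3 alone 1992. E14 and 3T3 without P19 shared 1492 regions, and P19 and 3T3 without E14 shared 501. A region was outside a line where the libraries of that line gave no overlapping peaks in it, so single peaks of either library could still lie there. Among the regions of E14 and P19, 14797 (80.8%) had no peak in either 3T3 library. Among the regions of a single line, those with no peak in any library of the other lines numbered 4604 in E14 (45.9%), 2668 in P19 (42.8%) and 755 in 3T3 (37.9%). The counts of regions held by a single line rest on both libraries of that line. Without E14 replicate 2, E14 alone held 28070 regions, more than the 21290 then held by E14 with P19, so the order of the combinations turned. Without P19 replicate 1, P19 alone held 17237, and without 3T3 replicate 1, 3T3 alone held 4362. The counts also moved with libraries of other lines. E14 alone held 5708 without P19 replicate 1, and P19 alone 3610 without E14 replicate 2. E14 with 3T3 held 541 without P19 replicate 1. P19 with 3T3 held 263 without E14 replicate 1 and 1041 without P19 replicate 1. The order also turned with the length of the lists. With 15462 peaks in every list, 3T3 alone held 5991 regions, E14 alone 2215, P19 alone 3120, E14 with P19 6454 and all 3 lines 2724.

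**Figure D2:**
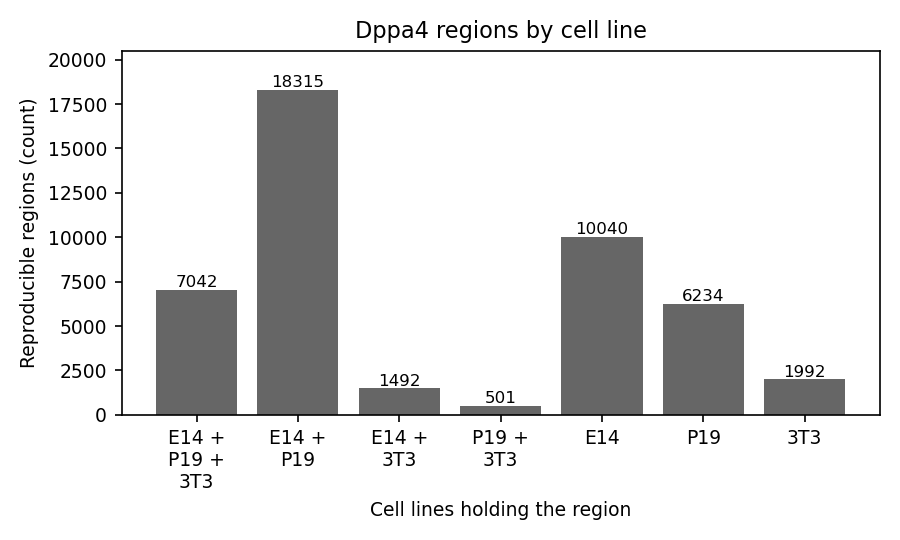
Number of reproducible Dppa4 regions (vertical axis, count) for each combination of cell lines (horizontal axis), with no replicate error because a region already requires both libraries of a line. The bar for E14 with P19 (18315) is the highest, and the bar for P19 with 3T3 (501) is the lowest.

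Most reproducible regions of the embryonic stem and the embryonal carcinoma cells overlapped between the 2 lines. Of the P19 regions, 79.4% (Wilson interval 78.9 to 79.8) overlapped an E14 region, and 91.0% overlapped a peak of at least 1 E14 library. Of the E14 regions, 68.8% overlapped a P19 region. Shifted regions gave 2.56% and 2.24% on average, so the observed shares were 30.9-fold and 30.8-fold above them (one-sided permutation p = 0.0099 for both, the smallest possible). Shifts that ignore open chromatin and mappability cannot tell shared DPPA4 sites from peaks that both lines would give without DPPA4. No immunoprecipitation from cells without Dppa4 was analysed here. Across the 4 pairings of single libraries, the share of P19 peaks found in E14 ranged from 67.8% to 81.6%. The share rose with the rank of the authors' peak score. Of the E14 regions in the lowest score decile, 24.5% were held by P19, against 99.4% in the highest decile. Of the P19 regions, 43.2% in the lowest decile and 99.5% in the highest were held by E14.

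With all peaks counted, most regions of the fibroblasts carrying ectopic Dppa4 were also regions of E14 or P19, but most regions of those lines were absent from the 3T3 set. Of the 3T3 regions, 77.6% (76.8 to 78.3) overlapped an E14 region and 68.3% (67.4 to 69.2) a P19 region. The shifted means were 3.09% and 2.52% (one-sided permutation p = 0.0099 for both, the smallest possible), with the same limit of the shifts. In the opposite direction, 23.6% of the E14 regions and 24.0% of the P19 regions overlapped a 3T3 region. These shares depend on the number of peaks per list. With every list limited to its 15462 best-scoring peaks, the share of 3T3 regions fell to 36.7% for E14 and to 33.7% for P19. Between E14 and P19 the smaller set was then that of E14. Of its regions 73.3% overlapped a P19 region, against 68.8% with all peaks. Single libraries of that equal length overlapped by 69.6% to 74.2% between E14 and P19, by 35.9% to 44.2% between E14 and 3T3, and by 33.4% to 39.4% between P19 and 3T3. The 3T3 libraries overlapped each other by 77.1% at that length. The ranges for E14 with P19 and for either line with 3T3 did not meet.

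The best-scoring 3T3 regions were nearly all present in the other lines, while most of the best-scoring E14 and P19 regions overlapped no reproducible 3T3 region. Of the 3T3 regions in the highest score decile, 98.4% were held by E14 and 95.6% by P19, against 61.3% and 57.7% in the lowest decile. Of the E14 regions in the highest decile, 33.2% (31.7 to 34.7) were held by 3T3, against 10.3% (9.35 to 11.3) in the lowest. For E14 the share was nearly level from decile 7, at 31.0%. For P19 regions the values were 32.7% (31.1 to 34.3) in the highest decile and 12.1% in the lowest, with no steady rise between them, since the share was 29.3% in decile 7 and 23.7% (22.3 to 25.2) in decile 9. This pattern belongs to reproducible 3T3 regions alone. The share with a peak in at least 1 of the 3T3 libraries rose further, from 40.2% in decile 7 to 65.9% in the highest decile for E14 regions and from 38.9% to 73.2% for P19 regions.

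**Figure D3:**
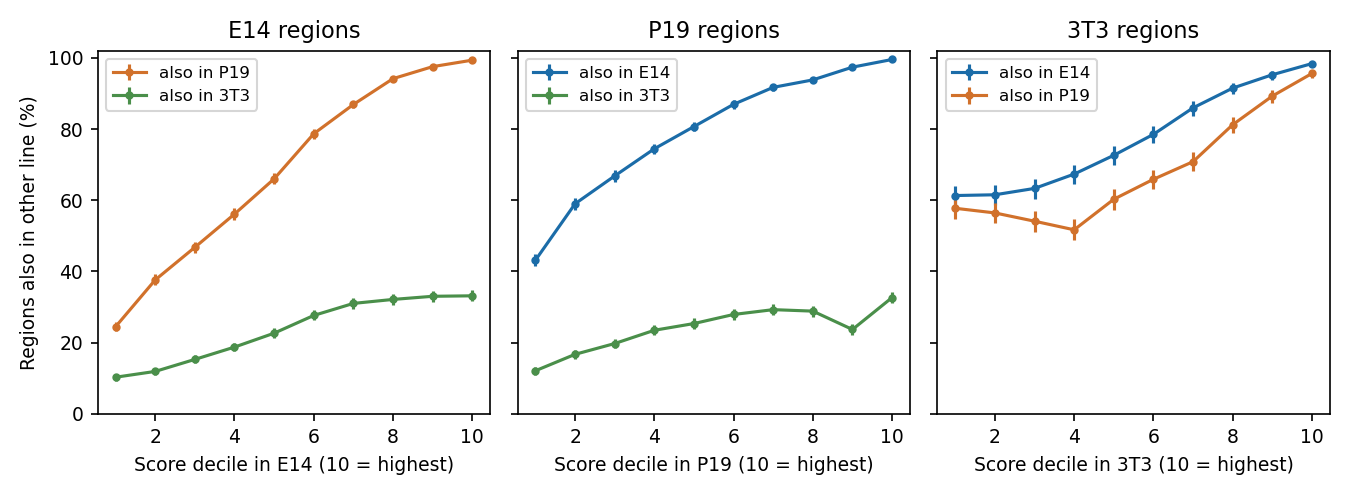
Share of the reproducible regions of E14, P19 and 3T3 (left, middle and right panels) that overlapped a reproducible region of another line (vertical axis, percent), by decile of the authors' peak score within the line (horizontal axis, 10 is the highest), with Wilson 95% intervals as bars. E14 and P19 contain nearly all of each other's best-scoring regions (99.4% and 99.5% in the highest decile), and 33.2% and 32.7% of these overlapped a reproducible 3T3 region.

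Regions held by all 3 lines ranked above regions held by a single line in every library. In E14 their median percentile was 81.0 and 75.6 in the 2 libraries, against 47.9 and 30.3 for regions of E14 alone. In P19 the medians were 67.4 and 75.5 against 32.5 and 43.5, and in 3T3 70.0 and 75.4 against 40.9 and 50.3. The difference had the same sign in 6 of 6 libraries (exact two-sided sign test, p = 0.031). The 2 libraries of a line enter the same definition of regions, so the 6 signs are not independent. Each region took the percentile of its best-ranked peak in a library. Regions of all lines were wider, with a median of 1328 bp against 676.5 bp in E14 alone, 515 bp in P19 alone and 839.5 bp in 3T3 alone. They could thus hold more peaks, which favours the direction found. Over the 7042 regions held by all lines, the order of scores was shared by the 2 libraries of a line, with Spearman rank correlations of 0.80 in E14, 0.88 in P19 and 0.86 in 3T3. The rank correlation ranged from 0.59 to 0.70 between E14 and P19 libraries, from 0.06 to 0.10 between E14 and 3T3 libraries, and from -0.15 to -0.08 between P19 and 3T3 libraries. These are correlations across regions, which are not independent replicates. Without the regions at 3100 or above in any library, the mean correlation of 3T3 with the other lines was 0.13, against -0.02 with them.

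The regions with the highest mean percentile in each combination can be placed in the mm9 assembly but were not assigned to genes. Scores are given as each list holds them, and their sizes can be compared only within a list. The first region of all 3 lines lay on chromosome 12 from 114013609 to 114023301, spanned 9693 bp and scored 3100 in 5 of the 6 libraries and 1268 in 3T3 replicate 1. The next ones were neighbours on chromosome 1, from 172998051 to 173005372 and from 173007595 to 173012504. The first region of E14 and P19 lay on chromosome 4 from 10620953 to 10622156. It scored 3100 or more in the 4 libraries of these lines, had no peak in 3T3 replicate 1 and scored 129 in 3T3 replicate 2. The next ones lay on the X chromosome, from 39057928 to 39059358 and from 165722856 to 165723969, each with a peak in 1 of the 3T3 libraries that scored under 100. The first region of E14 and 3T3 lay on chromosome 15 from 95682996 to 95684613, with scores of 1040 and 1873 in E14 and 753 and 952 in 3T3. It also had a peak in P19 replicate 1 that scored 138. The others lay on chromosome 18 from 7608767 to 7610101, with no P19 peak, and on chromosome 10 from 43198116 to 43200048, with peaks scoring 89.2 and 74.5 in the P19 libraries that did not overlap each other. The first region of P19 and 3T3 lay on chromosome 17 from 66713379 to 66714227, with scores of 882 and 950 in P19, 1141 and 1669 in 3T3, and 75.6 in E14 replicate 2. The others lay on chromosome 17 from 30023408 to 30026923, with a peak scoring 140 in E14 replicate 2, and on chromosome 11 from 85645274 to 85647361, with peaks scoring 102.2 and 180.04 in the E14 libraries that did not overlap each other.

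Among regions of E14 alone, the first ones lay on chromosome 18 from 15076388 to 15077341 and on chromosome 3 from 27639440 to 27640917. Both scored 3100 in both E14 libraries, had no P19 peak, and scored 51.1 and 73.8 in 3T3 replicate 2. The third lay on chromosome 17 from 35575440 to 35577601, with scores of 2250 and 1627 in E14, 54.3 in P19 replicate 1 and 97.2 in 3T3 replicate 2. Among regions of P19 alone, the first lay on chromosome 5 from 125646116 to 125647492 and scored 3100 in both P19 libraries, with peaks scoring 53.7 in E14 replicate 1 and 77.2 in 3T3 replicate 2. The second lay on chromosome 1 from 90101696 to 90102708, with scores of 2909 and 3100 in P19 and a peak scoring 226 in E14 replicate 2. The third lay on chromosome 2 from 174109469 to 174112669, with scores of 2076 and 3100 in P19, 101 in E14 replicate 2 and 105.4 in 3T3 replicate 2. Among regions of 3T3 alone, the first lay on chromosome 2 from 71366480 to 71368530, with scores of 593 and 1277 in 3T3, 87.0 in E14 replicate 2 and 78.3 in P19 replicate 2. The second lay on chromosome 17 from 13743094 to 13746466, with scores of 740 and 827 in 3T3 and 54.3 in E14 replicate 1. The third lay on chromosome 16 from 22438359 to 22440574, with scores of 600 and 862 in 3T3, 62.3 in E14 replicate 2 and 81.9 in P19 replicate 2.

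Peaks were spread over all autosomes and the X chromosome in every line, most densely on chromosome 11 and most sparsely on the X chromosome. Chromosome 11, known to be rich in genes, held 31.8 peaks per Mb in E14, 32.4 in P19 and 11.3 in 3T3. The X chromosome held 8.73, 7.77 and 1.88 peaks per Mb. As a share of the library's peaks, chromosome 11 took 7.35 ± 0.226% in E14, 8.65 ± 0.008% in P19 and 8.32 ± 0.197% in 3T3 (SD, n = 2). The X chromosome took 2.80 ± 0.272% in E14, 2.85 ± 0.105% in P19 and 1.87 ± 0.643% in 3T3 (SD, n = 2), and the 3T3 libraries differed from each other (1.42% and 2.33%). Chromosome 6 took 4.81 ± 0.155% in E14, 5.40 ± 0.024% in P19 and 5.59 ± 0.326% in 3T3 (SD, n = 2). To make the chromosome shares of 2 libraries alike, 1.33% of the peaks would have to move between the E14 libraries, 0.571% between the P19 libraries and 3.12% between the 3T3 libraries. Between lines the figure was 2.45% for E14 with P19 (range over 4 library pairs 2.29 to 2.63), 4.53% for E14 with 3T3 (3.24 to 5.85) and 3.85% for P19 with 3T3 (2.81 to 4.84). The spread between the 3T3 libraries thus lay inside the range between P19 and 3T3. Pairing by cell line gave the smallest mean of the 15 pairings, 1.67% against 2.62% for the next (exact permutation p = 0.067, the smallest possible).

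**Figure D4:**
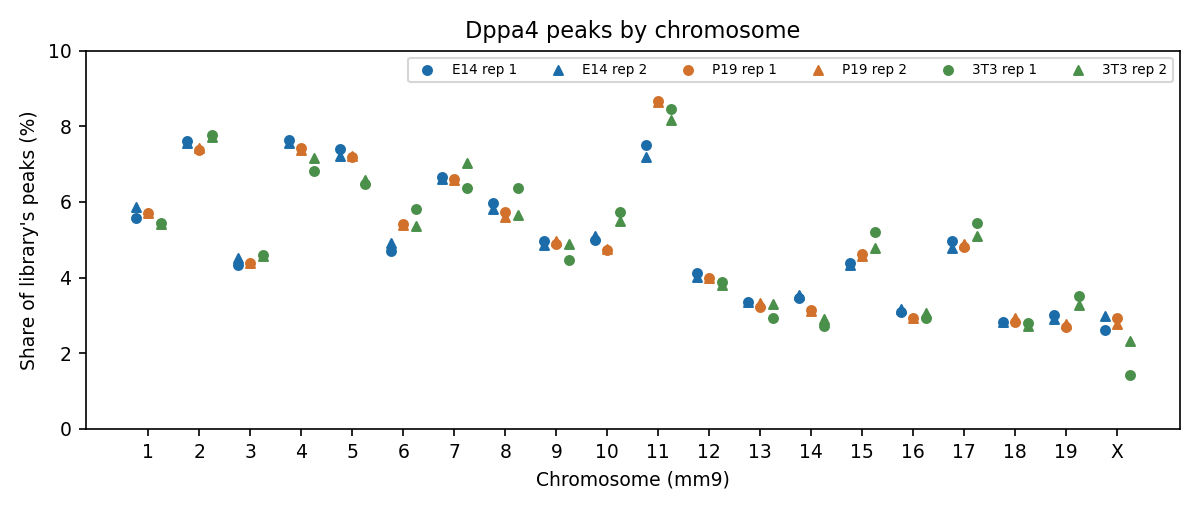
Share of each library's Dppa4 peaks (vertical axis, percent) on each chromosome of mm9 (horizontal axis), with circles for replicate 1 and triangles for replicate 2 of E14, P19 and 3T3. Chromosome 11 holds a larger share in both P19 libraries (mean 8.65%) than in both E14 libraries (mean 7.35%), and the X chromosome a smaller share in both 3T3 libraries (1.42% and 2.33%).

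Few peaks lay on the Y chromosome, counted together with its unplaced contigs. It held 261 and 203 peaks in E14, 120 and 144 in P19, and 9 and 17 in 3T3. This was 0.423% and 0.467% of the peaks in E14, 0.30% and 0.28% in P19, and 0.058% and 0.097% in 3T3. Unplaced contigs of any chromosome took between 0.559% and 0.795% of the peaks in the 6 libraries.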

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

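Every overlap between replicates and between lines stayed above all shifted lists under each alternative tried. Shifted lists gave at most 3.17% on average with all peaks, so this could hardly have gone otherwise and does not measure stability. Replicate overlap (mean of both directions) ranged from 75.2% to 82.2% in E14, from 75.6% to 86.5% in P19 and from 71.6% to 82.0% in 3T3. Lists of 15462 peaks lowered the shares with 3T3 to 36.7% (E14) and 33.7% (P19), from 77.6% and 68.3%. The share of P19 regions held by E14 was 82.3% without E14 replicate 1 and 87.7% without E14 replicate 2, against 79.4% with both. Leaving out a P19 library made E14 the smaller set. The share of E14 regions held by P19 was then 83.1% without P19 replicate 1 and 71.6% without P19 replicate 2, against 68.8% with both. Leaving out a library gave shares from 70.2% to 84.7% for E14 with 3T3 and from 62.5% to 81.8% for P19 with 3T3. With a replicate block, comparing libraries of the same number, the mean shares of the shorter list were 79.2% for E14 with P19, 76.3% for E14 with 3T3 and 69.6% for P19 with 3T3. The first is a mean of 81.6% of the P19 replicate 1 peaks and 76.7% of the E14 replicate 2 peaks. It therefore matches neither direction of the main comparison. With the block the shares likewise stayed above all shifted lists. Libraries of 2 lines with the same number had mean Jaccard indices of 0.489, 0.213 and 0.211 for these pairs of lines, against 0.471, 0.193 and 0.20 with different numbers. The labels give the numbers no shared origin. Counts of regions depended on the lists. With the best-scoring 50% of each list, all 3 lines held 2860 regions, E14 with P19 11181, P19 with 3T3 320, E14 alone 4677 and P19 alone 3791. With lists of 15462 peaks these counts were 2724, 6454, 837, 2215 and 3120, and 3T3 alone rose to 5991. Fewer peaks entered in both cases. Leaving out a library gave 7203 to 9858 regions for all 3 lines, 15498 to 22649 for E14 with P19, 541 to 2073 for E14 with 3T3 (541 without P19 replicate 1), and 263 to 1041 for P19 with 3T3 (263 without E14 replicate 1, 1041 without P19 replicate 1 and 823 without 3T3 replicate 1). It gave 5708 to 28070 for E14 alone (5708 without P19 replicate 1, 28070 without E14 replicate 2). It gave 3610 to 17237 for P19 alone (3610 without E14 replicate 2, 17237 and 9844 without P19 replicate 1 and 2). For 3T3 alone it gave 1436 to 4362 (4362 and 3543 without 3T3 replicate 1 and 2). A left-out library makes the other one stand for its line, so all of that library's peaks count. The mean gap in percentile between shared and single-line regions was 33.3 and ranged from 35.0 to 37.2 without a library. Its sign test then had 5 libraries and could not go below an exact two-sided p of 0.0625. The distance of chromosome shares between lines exceeded that within lines by 1.93% of peaks, by 3.43% in the best-scoring 50% and by 3.08% in lists of 15462 peaks; the cause was not tested. Alternatives for promoters, genes and gene lists were not run, for want of an mm9 annotation.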

Other observations

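The tests on the order of scores, and the stretches named in the next paragraph, were chosen only after the results were seen. Lists of equal length were an alternative fixed beforehand, but their use to test an explanation was chosen afterwards. The tests on regions without a 3T3 peak and on regions of 3T3 alone had been set out before.

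The densest run of peaks in every line lay on chromosome 6 of mm9. The E14 libraries held 112 and 65 peaks there, between 114347700 and 114715670, and the P19 libraries 105 and 88 peaks, between 114347616 and 114715705. The 3T3 libraries held 81 and 61 peaks, none of which reached beyond 114587622. In E14 replicate 1 this was 304 peaks per Mb, against 19.4 per Mb over chromosome 6. The median peak of the run ranked at percentiles from 47.2 to 72.5 in the 6 libraries. Most places with a peak wider than 8000 bp recurred between lists, such as chromosome 12 near 114013609 in 5 of the 6 lists and a series on chromosome 8 between 126060973 and 126148389 in both P19 libraries and in replicate 2 of E14 and 3T3. The places on chromosome 11 from 3026545 and on chromosome 6 from 47693162 were in 1 E14 list alone, and 3T3 replicate 1 held no peak of that width. Among 267 bins of 5 Mb with at least 20 peaks in each list, the end of chromosome 4 (150000001 to 155000000) differed most between P19 and E14, with 135 and 194 peaks in the P19 libraries and 496 and 315 in the E14 libraries. The ratio of shares there was -1.09 on the log2 scale, against a median of -0.02 over the bins. For 3T3 against E14 the lowest of these 267 bins was chromosome 4 from 140000001 to 145000000, at -0.98 on the log2 scale. The highest was chromosome 12 from 20000001 to 25000000, at 1.04, against a median of 0.13. Bins with few 3T3 peaks were left out by the limit of 20 peaks. Lower ratios could therefore go unseen, and the median may be raised.

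Most of the best-scoring regions of E14 and P19 overlapped no reproducible 3T3 region. A weaker 3T3 experiment is one possible explanation. Of the best-scoring 10% of regions shared by E14 and P19, 26.4% (670 of 2535, Wilson interval 24.8 to 28.2) lacked a peak in both 3T3 libraries. The bound set beforehand was 25%, which lies inside the interval, so a loss of sensitivity cannot be excluded as a contributor to the missing regions. A weaker experiment with the same order of sites at every rank is argued against by lists of equal length. These overlapped by a mean of 40.1% between E14 and 3T3, against 71.7% between E14 and P19 and 77.1% between the 3T3 libraries. The cut kept all of 3T3 replicate 1 and 15462 of the 17540 peaks of replicate 2, but only the best-scoring part of each E14 and P19 list. Weak 3T3 peaks thus entered, and a weaker experiment that lost the order of weak sites cannot be excluded. A difference between the cell lines, and binding of the antibody to other proteins, both stay open, since no immunoprecipitation from cells without Dppa4 was analysed here. The ectopic supply of Dppa4 in the 3T3 cells cannot be told apart from the line itself.

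Regions of 3T3 alone ranked below the wider regions of all lines within 3T3, at a median percentile of 44.1 over the 1992 regions (quartiles 30.5 and 58.5). They made up 6 of the 1102 best-scoring 3T3 regions. Only 1 of these 1102, or 0.091%, lacked a peak in all E14 and P19 libraries, but that criterion covers 755 of the 1992 regions, at a median percentile of 37.5 (quartiles 25.4 and 50.8). The share of 0.091% lay under the bound set beforehand as the outcome fitting low sensitivity in E14 and P19. The median percentile was not part of that bound. A share under the bound was likely under either explanation, since few 3T3 regions of any rank met the criterion, so the test decides little. Sites missed in E14 and P19 for low sensitivity and sites peculiar to 3T3 therefore cannot be told apart. Extra copies of chromosome segments in 3T3 would gather these regions, and the 53 fullest of 538 bins of 5 Mb held 40.3% of them, against 31.7% on average and at most 35.7% in 1000 random draws from all regions; the bound of 30% set beforehand for rejecting this lay below the random level and was set wrongly, so extra copies stay open.

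The order of scores over the 7042 regions of all lines was shared between E14 and P19 but hardly with 3T3. Noise in the 3T3 scores is argued against by a rank correlation of 0.86 between the 3T3 libraries. Ties at the top of the score scale are argued against as the whole cause. Without the regions at 3100 or above in any library, 6260 regions remained, and the mean rank correlation of 3T3 with the other lines was 0.13, against -0.02 with them. Over all 3T3 regions, presence in the other lines did differ with the 3T3 score. E14 held 61.3% and P19 57.7% of the lowest decile, against 98.4% and 95.6% of the highest. A candidate explanation is that the fibroblast line gives DPPA4 a different order among the regions held by all lines. The 3T3 cells carried Dppa4 ectopically, so an effect of the line cannot be told apart from an effect of the ectopic supply. No test of this candidate was possible with peak lists of these libraries alone, and copy number or local chromatin may also set scores.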
